A study of Drosophila melanogaster with 2 samples.

How the data were processed

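Chromatin was taken from whole embryos aged 0 to 24 h of a strain expressing a Poxn-eGFP fusion, precipitated and fragmented by Bioruptor sonication to a size range of 200 to 800 bp, per the labels. The labels conflict on the antibody, which is against GFP in the sample descriptions and given as Poxn in the antibody field. The former was used here, and with an antibody against Poxn the untagged protein would be precipitated too. The 2 libraries are biological replicates of 1 group, and replicate numbers were taken from the labels. A control experiment named in the labels was not analysed here. Read counts per library, the aligner, the peak caller and the IDR threshold are not given in the sources used here.

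The deposited files are peak lists on dm6. For each replicate and for the pair of replicates there is a ranked list of candidates and a thresholded list, and for the pair there is also a conservative version of both. Per the deposited notes, each list was made from the filtered alignments of its replicate or replicates and a further file shared by both replicates. The thresholded lists also derive from another shared file that is not named for the ranked lists, and the notes do not say what it is. Column 5 is a score from 0 to 1000 that the authors scaled from the irreproducible discovery rate (IDR). The signal value of each peak is the authors' enrichment value, and how it was normalised is not stated in the deposited files. The −log10 of the global IDR is given by the authors for each candidate, and no peak in the deposited thresholded lists was below 2, an IDR of 0.01. The deposited p-value column was constant and was not used. Signal and score were used only to describe and rank peaks within a list. The pair's thresholded list was the main set, with 1488 peaks, of which 1370 were 304 bp wide. It shared 1219 peaks by identical coordinates with the conservative list of 1353, and 269 and 134 peaks were in only the main or only the conservative list.

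Genes came from an Ensembl annotation of the BDGP6 assembly and sequence from the RefSeq assembly of the same release as dm6. There were 18277 gene models, 13945 of them protein-coding on the arms. Peaks off the arms, 39 of 1488, entered only the counts and signal summaries of lists and the overlap and correlation of replicates. Each summit was assigned in order of priority to promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, noncoding exon, intron or intergenic sequence. The background for classes, arms, words and 7-mers was every ranked candidate outside the main set, apart from 1 word of 11 bp, for which 20000 candidates were sampled. The background for gene lists was every protein-coding gene with a candidate summit within 500 bp of a TSS. Shares were compared by two-sided Fisher exact tests with Benjamini-Hochberg adjustment at 0.05 and 95% Wald intervals of the odds ratio, adding 0.5 where a cell was 0. Words were searched on both strands in 201 bp windows centred on summits. The matched background had 2 candidates per peak, drawn within promoter class and 5 GC bins. Overlap of replicates required at least 1 bp and was compared with 1000 relocations of the replicate 1 peaks on the arms. Medians and correlations were tested with 100000 permutations, or 1000 for correlations over all candidates.

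The groups, comparisons, tests, 20 gene lists, 14 words and the alternatives were fixed before the data were examined, apart from 4 added alternatives and the tests that the closing section names as chosen later. All 739 listed gene names were matched to the annotation, 11 of them through a renamed symbol. The chemoreceptor, ribosomal protein, translation factor and proteasome lists among them were set as symbol patterns, so their members match by construction. The text names genes by a rule that was fixed in the same way. It takes the nearest genes of the 20 strongest peaks, Poxn and w, and up to 4 members of each gene list with a peak, in order of signal. It also takes every fixed word, the 5 7-mers with the lowest p in each direction, and the 5 shared peaks with the largest rank difference between replicates. Genes named outside this rule are said to have been chosen after their values were seen. So were tun and CG32795, which are named only to place the peaks near Poxn and w.

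The alternatives were the conservative list, each replicate alone, the peaks of highest signal, a stricter IDR, other overlap rules, random positions, flanking windows or matched candidates as background, TSS windows of 250 and 1000 bp, the nearest TSS, all protein-coding genes or only candidates of highest signal as background, logistic regression on the number of TSSs and gene length, and 101 bp windows. Peaks and genes are not independent samples, so p-values describe these lists and not the variation between embryos. The procedures were tested on simulated data, and 18 of 18 checks passed. Some of these passed within a tolerance or on a p-value bound and not by recovering the exact value the data were made with. Of 100 random gene sets, 2 gave any call among the 20 lists. With 4-fold odds, a list of 59 ribosomal protein genes was called in 73 of 100 sets and a list of 19 sense organ genes in 14. These gene sets were drawn only from genes with a candidate outside the main set, which left 59 of the 72 ribosomal protein genes tested. They therefore only approximate the tests that were run. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.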

Results

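Binding of Pox neuro (Poxn), a paired-domain transcription factor known for specifying chemosensory sense organs, was mapped by chromatin immunoprecipitation and sequencing in whole Drosophila melanogaster embryos aged 0 to 24 h. The embryos carried a Poxn-eGFP fusion, and chromatin was precipitated with an antibody against GFP, per the sample descriptions, whereas the antibody field of the labels names Poxn. There were 2 biological replicates in 1 group and no control group analysed here, so no test between groups of samples was possible. The values are peak positions and peak signal values as the authors' files give them, on the dm6 genome build. Signal values rank peaks within a list only. Read depth per library is not given in the sources used here, so its effect on the number of peaks is unknown.

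The list used as the main set held 1488 peaks, 1.02% of the 146020 ranked candidates from which it was drawn, and covered 435.6 kb. Its median signal was 81.2, with a range of 2.03 to 1086, against a median of 16.8 over all candidates. Replicate 1 alone gave 800 peaks and replicate 2 alone gave 979. The 1449 peaks on the chromosome arms entered all comparisons with annotated genes and sequence.

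The peaks with the highest signal lay at promoters, within 500 bp of a transcription start site (TSS), and in introns. The first was at CG14100, with a signal of 1086, and the second at mRpL41, which encodes a protein of the mitochondrial ribosome, with a signal of 1020. Of the 20 strongest peaks, 14 were at promoters and 6 in introns, and all 20 overlapped a peak in the list of each replicate. The peak at CG14100 spanned 3L 19590484 to 19590761, with its summit 91 bp upstream of the TSS. The peak at mRpL41 spanned 2R 15217611 to 15217884, with its summit 142 bp upstream. Intronic peaks followed in CG11050 (2L 6612588 to 6612842, signal 918), in HmgZ (2R 21703238 to 21703578, signal 761), which encodes an HMG-box chromosomal protein, and in Adf1 (2R 6662938 to 6663180, signal 724), which encodes a sequence-specific transcription factor. The promoter of Ugalt, a UDP-galactose transporter gene, carried a peak at X 2703763 to 2704013 with a signal of 901. Trl, which encodes the GAGA factor, had an intronic peak at 3L 14759388 to 14759650 with a signal of 612.1. The promoter of ph-p, which encodes a Polycomb group protein, had a peak at X 2137242 to 2137457 with a signal of 612.0. Chro, which encodes the chromodomain protein Chromator, had a promoter peak at 3L 22878785 to 22879007 with a signal of 535. The promoter of mRpS10, another mitochondrial ribosomal protein gene, had a peak at 3R 15229420 to 15229652 with a signal of 614. The promoter peak of the antisense RNA gene asRNA:CR45928, at 2R 23850293 to 23850519 with a signal of 669, also lay within 500 bp of a TSS of eIF6, a translation factor gene. The other 9 were promoter peaks nearest to lncRNA:CR44619, Tcs5, CG5611, CG7601, CenG1A, CG13390 and Atat, and intronic peaks in CG9663 and CG32772, with signals between 504 and 707.

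The replicates shared most of the sites in the shorter list. Of the 800 peaks of replicate 1, 588 (73.5%) overlapped a replicate 2 peak by at least 1 bp, and 585 of the 979 replicate 2 peaks (59.8%) overlapped a replicate 1 peak. Relocating a list at random within its chromosomes 1000 times gave a mean of 3.14 shared peaks and at most 10 (one-sided permutation test, p = 0.001, the smallest that 1000 relocations can give). Equally many candidates drawn at random shared 7.60 on average and at most 18. In the main set, 583 peaks (39.2%) overlapped both replicate lists, 173 overlapped only the list of replicate 1, 324 only that of replicate 2, and 408 (27.4%) neither. The median signal was 143 for peaks in both lists and 59.97 for peaks in neither. For differences in rank, the 577 shared sites were ranked among themselves in each replicate and not within the whole lists. The 5 with the largest difference were nearest to Eogt (rank 492 in replicate 1 and 76 in replicate 2), aru (563 and 190), Rtnl1 (473 and 117), Cds (505 and 169) and Ptpmeg2 (136 and 463).

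Peak height was correlated between the replicates across the 1478 main-set peaks for which a ranked list gave both values (Spearman's rho = 0.591, Pearson's r = 0.679 on the log2 scale). The main set was itself selected by the irreproducible discovery rate, a measure of agreement in rank between lists, so this correlation is conditional on that selection and describes the selected peaks only. Peaks are also not independent replicates. Both values came from the conservative ranked list. It does not name its compared lists, and 65.7% of the coordinates in the first equalled replicate 1 candidates and 69.1% of those in the second equalled replicate 2 candidates. In the ranked list of the main set, at most 0.00137% of the coordinates in a compared list equalled candidates of either replicate. Which lists were compared to select the main set is therefore not known, and they need not be the 2 replicate lists. Over all 144729 candidates of the conservative ranked list rho was 0.225, and over the 143251 outside the main set, a setting added after seeing the data, it was 0.203 (two-sided permutation tests with 1000 permutations, p = 0.000999 for both, the smallest they can give). The deposited notes name a further file shared by both replicates, so the replicate lists are not fully independent.

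**Figure D1:**
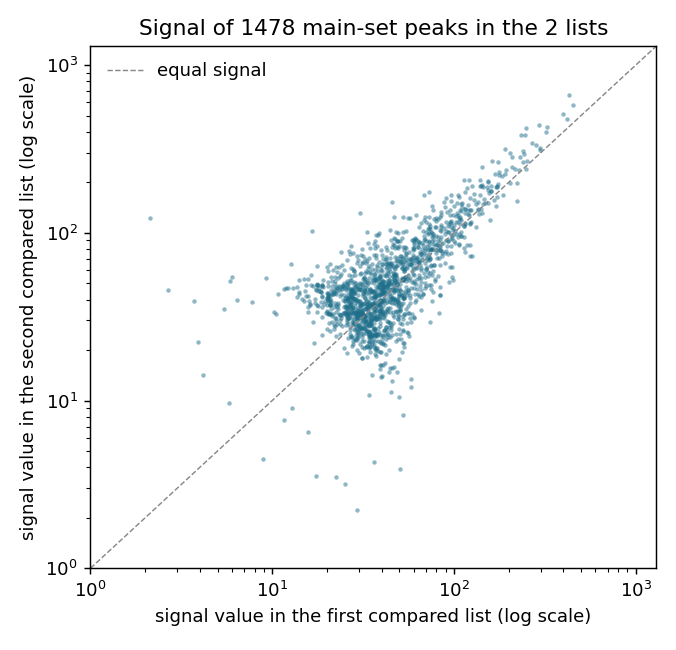
Signal value of each of 1478 main-set peaks in the first compared list of the conservative ranked list (x axis, log scale) and in the second (y axis, log scale), 1 point per peak, with the dashed line at equal signal. Spearman's rho across these peaks was 0.591.

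Poxn-eGFP peaks were concentrated at promoters and rare in coding sequence. Summits within 500 bp of an annotated TSS made up 821 of the 1449 peaks (56.7%), against 13.5% of the 141821 candidates outside the main set (odds ratio 8.40, 95% interval 7.57 to 9.34). Coding exons held 23 peaks (1.59% against 18.9%, odds ratio 0.0691, 95% interval 0.0457 to 0.104). Introns held 434 peaks (29.95% against 37.9%, odds ratio 0.701), intergenic sequence 145 (10.01% against 25.3%, odds ratio 0.329) and 3' UTRs 5 (odds ratio 0.126). These 5 classes passed two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 7 classes, with adjusted p from 4.87e-10 downward. The two-sided p for promoters was too small to be stored, and the one-sided p had a −log10 of 320.4. For 5' UTRs (7 peaks, exact adjusted p = 0.109) and noncoding exons (14 peaks, adjusted p = 0.566) no difference was detected. The coding exon odds ratio ranged from 0.00592 among the peaks of highest signal to 0.102 against random positions, where that of 3' UTRs was 0.0735, and stayed below 1 under every alternative tried.

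Within promoters the summits lay mostly upstream of the TSS. Of the 821 promoter summits, 684 (83.3%) were upstream of the nearest TSS, against 41.1% of candidate promoter summits (odds ratio 7.17, 95% interval 5.95 to 8.63, two-sided Fisher exact test, p = 1.38e-131). The median position was −121 bp, whereas the median candidate lay 73 bp downstream. Promoter peaks were also higher, with a median signal of 89.54 against 75.002 for the other 628 peaks, a difference of 14.5 (two-sided permutation test, 100000 permutations, p = 1e-05, the smallest they can give). On the signal scales of the single replicates the difference was 8.92 in replicate 1 and 8.13 in replicate 2. Windows reaching 100 bp to either side of main-set summits had a median GC content of 34.8%, against 46.3% in candidates, and the values at promoters alone were 33.8% and 46.8%.

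**Figure D2:**
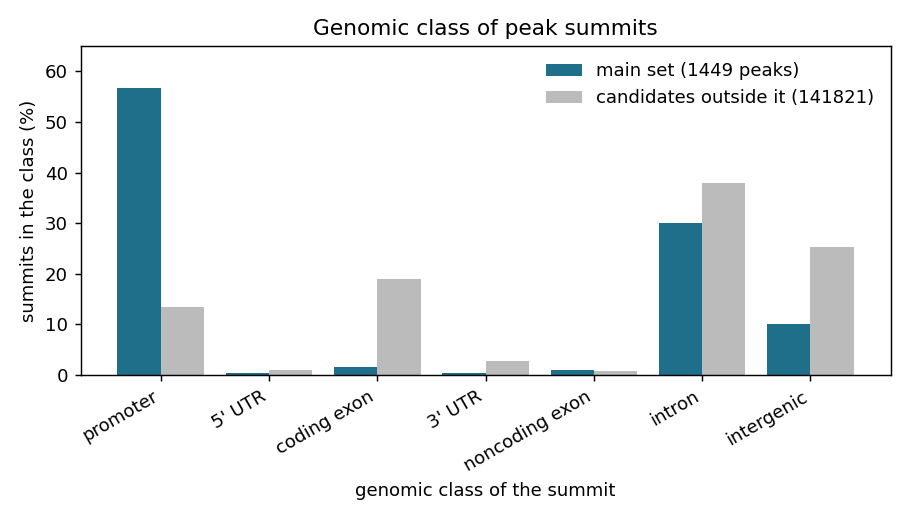
Share of summits (y axis, percent) in each of 7 genomic classes (x axis) for the 1449 main-set peaks on the arms and the 141821 candidates outside the main set. The promoter class holds 56.7% of the peaks and 13.5% of the candidates.

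Among the chromosome arms, 3R carried fewer peaks than its share of candidates and X carried more. Arm 3R held 300 peaks (20.7% against 25.7%, odds ratio 0.757, 95% interval 0.666 to 0.860, exact adjusted p = 9.05e-05). Arm X held 287 (19.8% against 17.1%, odds ratio 1.199, 95% interval 1.05 to 1.37, exact adjusted p = 0.0190), and Y held 0 peaks against 546 candidates (adjusted p = 0.0190). These are two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 7 arms. Among the peaks of highest signal neither the X nor the Y difference was called (odds ratios 1.24 and 0.178, exact adjusted p = 0.0903 and 0.216), and against random positions arm 4, with 1 peak, was called as well (adjusted p = 0.000103). The Y difference was called in neither replicate alone (odds ratio 0.424, exact adjusted p = 0.645 in replicate 1, and 0.266, adjusted p = 0.475 in replicate 2).

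Main-set peaks lay at promoters of cytoplasmic ribosomal protein genes more often than at other promoters, and at 0 of the 175 chemoreceptor promoters tested. Of 10819 protein-coding genes with a candidate summit within 500 bp of a TSS, 1079 (9.97%) had a main-set summit there. For ribosomal proteins the count was 25 of 72 (34.7% against 9.81%, odds ratio 4.89, 95% interval 2.999 to 7.98, exact adjusted p = 1.36e-07). The highest signals among them were at RpL7 (200.99), RpL34b (187), RpL32 (168) and RpS27 (159). For the chemoreceptor families, which hold odorant, gustatory and ionotropic receptors and odorant-binding proteins, the count was 0 of 175 against 10.1% (upper 95% limit of the odds ratio 0.406, exact adjusted p = 1.36e-07). These were the only 2 of 20 lists past two-sided Fisher exact tests with Benjamini-Hochberg adjustment over the lists. The counts are of peaks, and whether open promoter chromatin rather than binding by Poxn gives these 2 differences was not tested. The ribosomal odds ratio was 2.54 in replicate 2 alone and 2.50 against the candidates of highest signal, where it stayed past the threshold (exact adjusted p = 0.0462 and 0.0231). With each peak assigned to its nearest TSS at any distance, 2 of 209 chemoreceptor genes had a peak.

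The list of chromatin insulator, Polycomb and Trithorax factors also holds other transcription factors, Dref among them. Its genes carried a peak in 6 of 19 cases (31.6%, odds ratio 4.18, 95% interval 1.59 to 11.0, exact adjusted p = 0.0561). The 6 included ph-p (signal 612.0), brm (332), which encodes the ATPase of the Brahma chromatin remodelling complex, Cp190 (197), which encodes an insulator protein, and E(z) (137), which encodes a Polycomb group histone methyltransferase. This list passed the threshold in replicate 2 alone (7 of 17, odds ratio 6.81, exact adjusted p = 0.00521) and not in replicate 1 alone (4 of 19, odds ratio 3.91, adjusted p = 0.1496), where the odds ratio was close to that of the main set. Its adjusted p ranged from 0.00446 to 0.328 over the alternatives tried. Translation factors had peaks at 7 of 31 genes (odds ratio 2.64, exact adjusted p = 0.1498), with the highest signals at eIF6 (669), eIF4EHP (342), eEF1gamma (109) and eIF3c (108). They passed the threshold among the peaks of highest signal (exact adjusted p = 0.0414, range over the alternatives 0.0414 to 0.632). The peak at RpL13 also served Dref, which is among the 6 genes counted for the chromatin list. That at RpL28 also served eIF1, and both Dref and eIF1 were named after their values were seen. The summits counted for brm, Cp190 and eIF4EHP lay 152, 173 and 223 bp from their TSSs. Each was nearer to the TSS of another gene, at 114, 108 and 153 bp. The peak at eIF4EHP overlapped no peak in the list of either replicate. Such sharing is not given here for every member of the lists, so a counted peak need not belong to the listed gene. Proteasome subunits had 3 of 36 (Prosbeta2, Rpn5 and Rpn3, odds ratio 0.820, exact adjusted p = 1).

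For the lists tied to the known role of Poxn no enrichment was detected. The chromatin was from whole embryos, so sites particular to a few cells were not assessed separately. Of 19 sense organ genes, 1 had a peak (odds ratio 0.501, 95% interval 0.0668 to 3.76). This was numb, a regulator of Notch signalling in asymmetric division, with a peak at 2L 9449466 to 9449769 and a signal of 169. Pax and paired-type genes had 0 of 6, neuroblast factors 0 of 22 and homeotic genes 0 of 11. The Notch pathway had 5 of 21 (odds ratio 2.83, 95% interval 1.03 to 7.74, exact adjusted p = 0.206), with signals of 203 at gro, a corepressor gene, 169 at numb, 86.3 at E(spl)m3-HLH and 85.8 at aph-1. The summit counted for aph-1 lay 415 bp from its TSS and 153 bp from that of another gene. Neuronal differentiation genes had 1 of 21 (elav, signal 302), and axon guidance genes 3 of 20 (trio, 110.2, Sema1a, 106, and unc-5, 59.9). The lists of other tissues gave 2 of 22 segmentation genes (fkh and nkd), 1 of 24 appendage genes (Dll), 2 of 21 muscle genes (sls and tin), 1 of 11 glial genes (moody), 2 of 15 tracheal and salivary gland genes (fkh and trh), 1 of 17 gut, fat body and blood genes (fkh), 0 of 17 epidermal genes and 1 of 12 germline genes (piwi). None of these lists passed the threshold, with adjusted p from 0.206 upward. With each peak assigned to its nearest TSS at any distance, several of them turned from below to above an odds ratio of 1, with 6 of 25 appendage genes (2.97 in place of 0.392, exact adjusted p = 0.113), 6 of 21 muscle genes (3.77 in place of 0.950, adjusted p = 0.0603), 3 of 13 germline genes (2.82 in place of 0.820) and 4 of 24 segmentation genes (1.88 in place of 0.903). Glial genes (1.56 in place of 0.903) and gut, fat body and blood genes (1.04 in place of 0.564) turned as well. The direction of such short lists also turned under other alternatives, and none of these lists passed the threshold under those tried. On simulated gene sets with 4-fold odds, a list of the size of the sense organ list was called in 14 of 100 cases. Differences of that size were thus mostly not detected in short lists there. The simulation used only genes with a candidate outside the main set, so it approximates the test that was run.

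**Figure D3:**
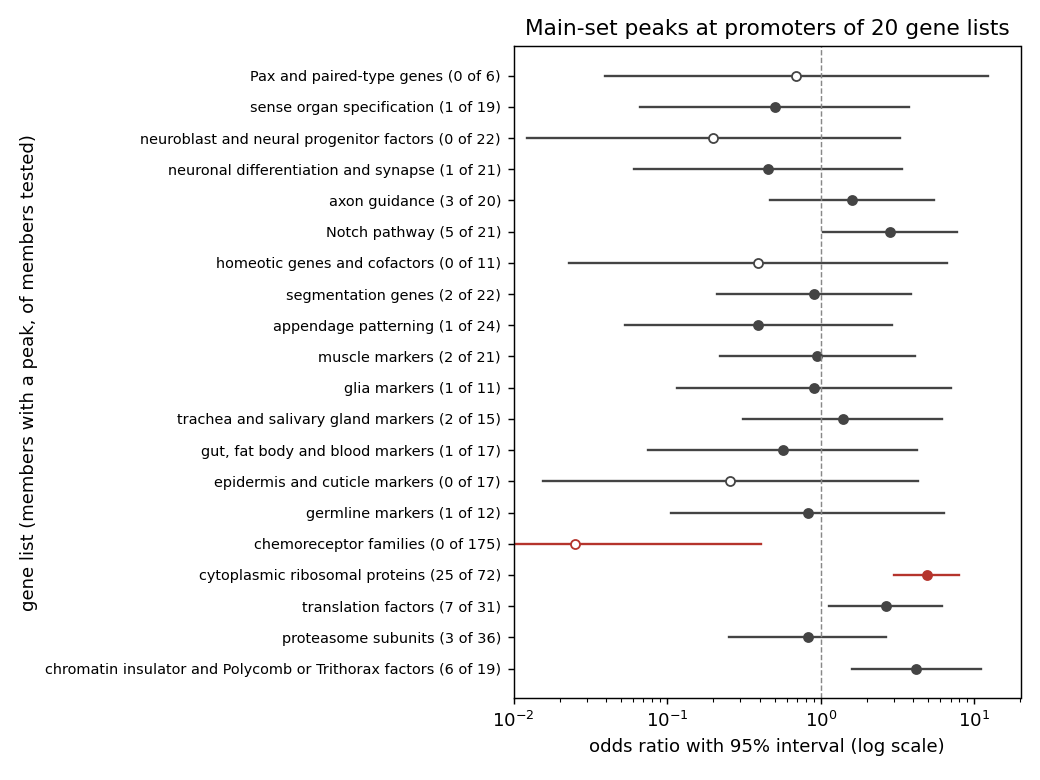
Odds ratio (x axis, log scale) of a main-set peak within 500 bp of a TSS for each of 20 gene lists (y axis, with the members that have a peak and the members tested), with 95% intervals as bars. Red marks the 2 lists past the threshold, 25 of 72 ribosomal protein genes and 0 of 175 chemoreceptor genes. Open circles mark lists in which 0 members had a peak.

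GTCACGC, the core word of Pax2/5/8 sites, did not differ detectably in frequency between Poxn-eGFP summits and other candidates. It occurred in 17 of the 1449 summit windows (1.17%) and in 1.21% of candidate windows (odds ratio 0.973, 95% interval 0.602 to 1.57, two-sided Fisher exact test, p = 1). Against candidates matched on promoter class and GC content the odds ratio was 1.17 (95% interval 0.643 to 2.14, exact p = 0.638). With 20 GC bins, a setting added after seeing the data, it was 1.55 (95% interval 0.822 to 2.93), so a moderate enrichment was not excluded. A longer form of this site, of 11 bp, with up to 1 mismatch had an odds ratio of 0.960 (95% interval 0.468 to 1.97) against 20000 sampled candidates. These were not matched on promoter class or GC content, so this value is comparable only with the unmatched one. The sequence that Poxn itself prefers was not available in the sources used here, so these values concern the Pax2/5/8 site and leave open whether Poxn-eGFP summits hold a Poxn site.

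Of 14 fixed words, 9 differed from candidates after Benjamini-Hochberg adjustment over the words. Higher were TATAAA, the TATA box (35.4% against 15.1%, odds ratio 3.09), TATCGAT, the DREF site (odds ratio 2.88), GGTCACAC, the core promoter word Motif 1 (2.77), TAATTA, a homeodomain word (1.956), AAAAAAAA (1.86) and GAGAGAG, the GAGA factor word (1.53). Lower were ACACACAC (0.434) and the E-boxes CATCTG (0.462) and CAGCTG (0.746). The Zelda word CAGGTAG (0.950), the E-box CACGTG (0.730), the AP-1 word TGACTCA (1.44) and CCCTATA (1.503) did not pass the threshold. Against candidates matched on promoter class and GC content only 3 words passed, CATCTG (0.618, exact adjusted p = 0.00728), GAGAGAG (1.69, adjusted p = 0.0386) and TATAAA (1.199, adjusted p = 0.0386), the last of which was lost with 20 GC bins (1.11, adjusted p = 0.273). With matching in 5 bins the words no longer called were at 1.23 for TATCGAT, 1.36 for GGTCACAC, 1.0497 for TAATTA, 0.915 for AAAAAAAA, 0.873 for ACACACAC and 1.171 for CAGCTG. GAGAGAG was called in neither replicate alone, with odds ratios of 1.34 in replicate 1 (exact adjusted p = 0.198) and 1.44 in replicate 2 (adjusted p = 0.0602) that were close to the 1.53 of the main set. It was also not called among the peaks of highest signal (1.24, exact adjusted p = 0.390). GGTCACAC was not called in replicate 1 alone (2.19, exact adjusted p = 0.0808) or against flanking windows (2.01, adjusted p = 0.0783). In the narrower windows tried as an alternative the odds ratios fell below 1 and were not called, at 0.705 for GAGAGAG (exact adjusted p = 0.302) and 0.979 for GGTCACAC (adjusted p = 1). CAGCTG was not called against random positions (0.966, exact adjusted p = 0.798) or flanking windows (0.813, adjusted p = 0.118). Among the peaks of highest signal CACGTG (0.435, exact adjusted p = 0.0103) and TGACTCA (1.76, adjusted p = 0.0237) passed, as they did against the candidates of highest signal (exact adjusted p = 0.00664 and 0.0309). Both passed in replicate 2 alone (0.522 and 1.697, exact adjusted p = 0.0144 and 0.0242) and neither in replicate 1 alone (0.724 and 1.14, adjusted p = 0.294 and 0.606), and against matched candidates CACGTG was at 1.054. Against windows 500 bp to either side of the same summits GAGAGAG was lower, with an odds ratio of 0.667 (exact adjusted p = 0.0224).

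**Figure D4:**
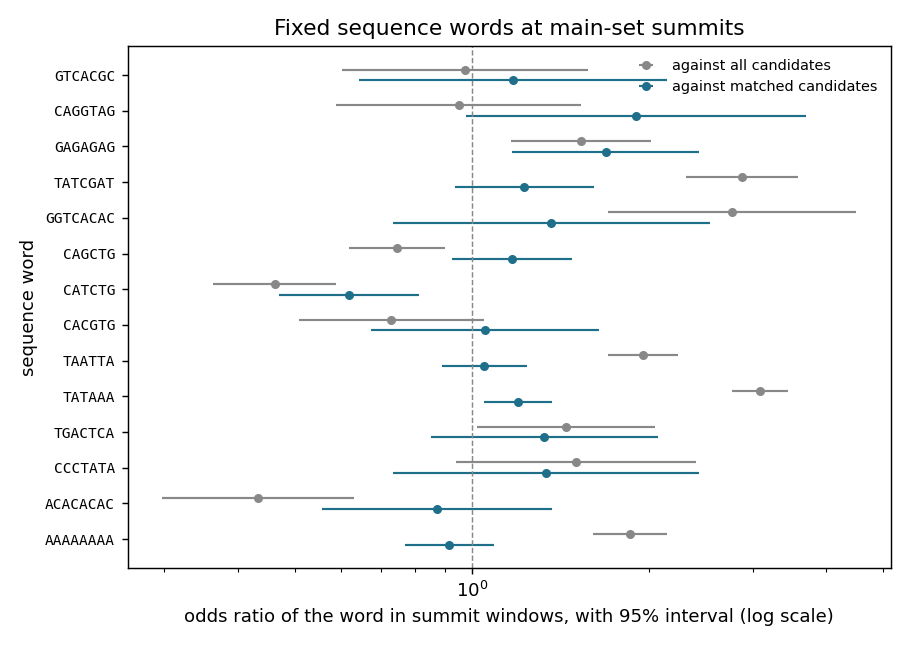
Odds ratio (x axis, log scale) of each of 14 fixed words (y axis) in main-set summit windows against all candidates (grey) and against candidates matched on promoter class and GC content (blue), with 95% intervals. The odds ratio of TATAAA moves from 3.09 to 1.199 with matching.

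Without a preset word, 3635 of 8192 7-mers differed between peaks and candidates, 1338 higher and 2297 lower (two-sided Fisher exact tests, Benjamini-Hochberg adjustment). The 5 higher words with the lowest p were TTTAAAA, in 25.7% of peaks against 7.04%, AAAATAT, TTAAAAA, TAAAATA and AAAAATA. The 5 lower words were CTCCTCC, in 0.828% against 5.56%, TGGCCAA, CTGGCCA, CGAGGAG and CTGCTGC. With candidates matched on promoter class and GC content, 86 7-mers passed the threshold, 68 higher and 18 lower. Their first word was ACAGTGG, in 161 peaks (11.1%) against 2.80% (odds ratio 4.35, 95% interval 3.30 to 5.72, exact adjusted p = 1.66e-23), followed by CACTGTA, CACAGTG, ACTGTGC and CAGTGCA with odds ratios between 2.97 and 4.29. In windows simulated from candidates with the GC content of the peaks, 3186 7-mers were called without matching and 0 with it. These windows were drawn on GC content alone. They do not show whether the 86 7-mers reflect position relative to the TSS, which was not matched.

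The Poxn gene itself carried no main-set peak. Within 20 kb of Poxn (2R 15826693 to 15835055) there was 1 main-set peak, at 2R 15847824 to 15848127 in an intron of tun, with a signal of 56.4. Its site was in the list of replicate 1 and not in that of replicate 2, nor in the conservative list. The 61 candidates within 20 kb placed Poxn at percentile 81.5 of 13945 protein-coding genes. The white gene (w, X 2790599 to 2796466), a common marker of fly transgenes, also had 0 main-set peaks within the gene or 500 bp of it. Within 20 kb of w there were 2, at X 2786616 to 2786919 (signal 157) and X 2787277 to 2787580 (signal 87.3), both in an intron of CG32795. The 54 candidates there placed w at percentile 57.6. No p-value was computed for these percentiles.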

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

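The tests of unplaced sequence and of head-to-head promoters were chosen only after the results they address were seen, and those of the Poxn and white genes and of the Pax2/5/8 core word at promoters were set before.

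The thresholded list leaves out 118 candidates whose deposited IDR is past its own threshold, so that 1606 candidates pass and 1488 are listed. Of the 118, 34 lie off the chromosome arms, against 39 of the 1488 listed peaks, all 39 of them on 34 unplaced scaffolds of X. Another 24 lie toward one end of X, at 23216979 to 23404946. Their nearest annotated TSS was that of a ribosomal RNA gene or pseudogene, at distances from 2679 to 113095 bp. The strongest, with a signal of 868, would have rank 5 in the main set and lies in an intron at 2L 480965 to 481228, nearest to the TSS of cbt. It was followed by candidates near Lk6 (594), larp (364), tara (257) and trx (251), all genes named after their values were seen. Scaffolds and that end of X together held 49.2% of the 118, under the 75% set as the bound against their accounting for the whole group. Other chromosome ends were not counted, and whether other repeats are among the 118 was not tested. The thresholded lists also derive from a shared file that the notes do not identify. Whether that file removed these candidates is unknown.

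Main-set peaks were concentrated at promoters, and with 1 group in the design no biological difference between groups could be tested. Open promoter chromatin, rather than recognition of a sequence by Poxn, could give this. The Pax2/5/8 core word had an odds ratio of 1.17 against matched candidates (95% interval 0.643 to 2.14), which also allows an enrichment, and the sequence that Poxn itself prefers was not available, so the explanation stays open although the interval includes 1, as set beforehand for it. Head-to-head gene pairs made up 37.0% of promoter summits against 7.66% of candidate ones (odds ratio 7.09). With summits restricted, after that value was seen, to 50 to 200 bp upstream of a TSS, they made up 48.6% against 15.3% (odds ratio 5.23, 95% interval 4.21 to 6.51), but this recounts part of the same peaks, so a preference for such promoters stays a hypothesis that was not tested on other peaks.

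Extra copies of the Poxn region on a transgene, or of white as its marker, could raise signal at those genes without binding. The count of candidates within 20 kb lay at percentile 81.5 of genes for Poxn and 57.6 for white, both below the bound of 95 set against the explanation. For white that bound also asked for no main-set peak, which holds for the gene (0) and not for the 20 kb around it (2, in CG32795), and the gene was taken as its meaning only after these values were seen. The median candidate signal within 20 kb, a value added afterwards, was 13.2 at white (percentile 2.17 of genes) and 19.2 at Poxn (percentile 76.8) against a median of 17.6 over genes, so neither gene passed percentile 95 of genes by count or by signal. Per kb, which allows for gene length, the candidate counts lay at percentile 65.5 for Poxn and 48.4 for white. Extra copies need not add candidate positions, so the counts are a weak test of them. Copies also present in a control library would not show in the counts or the signals.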

How the results depend on the processing

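The alternatives without overlapping peaks, with the unlisted candidates, with 20 GC bins and with the correlation outside the main set (rho 0.203) were added after seeing the data. Of 103 alternative values of the main results 85 kept their direction and side of the threshold, 13 moved and 5 reversed. Of 540 alternative odds ratios of single lists, words, classes and arms, 455 were the same, 45 moved, 19 lost and 13 gained a call, and 8 reversed. The share of promoter peaks lay between 45.1% and 67.8% and was called under all alternatives run for it. Leaving out a replicate gave 800 to 979 peaks, a Pax2/5/8 core odds ratio of 0.749 to 1.201, and 0 to 1 peaks within 20 kb of Poxn. The conservative list and the peaks of highest signal also gave 0 there. The latter held 744 peaks by construction, and called 1 arm in place of 3 and 4 gene lists in place of 2. The Pax2/5/8 core odds ratio, never past the threshold, was above 1 against random positions (1.34), flanking windows (1.17), matched candidates (1.17) and those in 20 GC bins (1.55). Called words fell from 9 to 3 with matching and to 2 with 20 bins, and called 7-mers from 3635 to 86 and 66, or 1664 against flanks. In simulated windows of the same GC content, calls fell from 3186 to 0 with matching. Matching also cut the background to 2 candidates per peak, and these 2 changes were not separated. The GAGAGAG odds ratio was 0.705 in windows reaching 50 bp to either side and 0.667 against flanks, and GGTCACAC was at 0.979 in the former. With matching in 5 and 20 bins CAGCTG was at 1.17 and 1.26 and AAAAAAAA at 0.915 and 0.920, and TAATTA was at 0.988 in 20 bins. For the other changes the cause was not tested. Read depth is unknown, so whether it limited the number of weak sites in each replicate was not tested.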

Other observations

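All tests in this part were chosen after the results were seen, and they were added to the planned comparisons.

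Main-set summits lay within 500 bp of an ncRNA TSS in 64 cases, 28 of them also within 500 bp of the TSS of a protein-coding gene. Over all peaks this was more than in candidates (4.42% against 2.19%, odds ratio 2.07, 95% interval 1.61 to 2.66), but less so than for protein-coding genes (54.2% against 11.3%, odds ratio 9.26). Among promoter summits alone ncRNA genes were less frequent than in candidates (64 of 821, 7.80%, against 16.2% of 19090, odds ratio 0.436, 95% interval 0.337 to 0.564, two-sided Fisher exact test, p = 3.00037e-12). For tRNA genes there were 4 summits (odds ratio 2.35, exact adjusted p = 0.193). The whole lists of replicates 1 and 2 had 58.4% and 65.8% of their arm peaks at promoters. Of the 203 arm peaks found only in replicate 1, 86 (42.4%) were at promoters, and of the 382 found only in replicate 2, 251 (65.7%) were (odds ratio 2.61, 95% interval 1.84 to 3.70, two-sided Fisher exact test, p = 7.14e-08), which compares these 2 libraries and no condition. In the main set, 40 peaks overlapped a stronger peak, with a median signal of 6.21, and 37 of the 38 peaks with a signal under 30 were among them.

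A sequence word shared by the sites may account for the 7-mers that exceed matched candidates. The word with the lowest p on arms 2L, 3L and X was again ACAGTGG, and on arms 2R and 3R it occurred in 10.4% of peaks against 2.57% of candidates matched in 20 GC bins, the setting added after seeing the data (odds ratio 4.39, 95% interval 2.82 to 6.83), although it had first been seen on all arms together. It was found in 16.4% of the strongest and 7.04% of the weakest 483 peaks (odds ratio 2.58, 95% interval 1.69 to 3.95), in line with a word that goes with height. Copies lay within 25 bp of the summit in 9.77% of cases against 26.0% in those same matched candidates (odds ratio 0.309, 95% interval 0.151 to 0.630), which argues against a word that marks the summit itself. Which protein recognises ACAGTGG was not tested. The matching did not cover position relative to the TSS. Promoter summits lay upstream in 83.3% of main-set cases against 41.1% of candidate ones. A word of upstream promoter sequence would also be more frequent on all arms, so the arms 2R and 3R cannot separate it from a word particular to these sites.

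Genes of mitochondrial ribosomal proteins could be a further group with promoter peaks, a hypothesis raised by their presence among the strongest peaks. With all of them, 11 of 56 had a promoter peak (odds ratio 2.22, 95% interval 1.14 to 4.30, two-sided Fisher exact test, p = 0.0235). Without those at the 20 strongest peaks, which had raised the hypothesis, 8 of 53 did (odds ratio 1.61, 95% interval 0.757 to 3.42, two-sided Fisher exact test, p = 0.244). The genes left out all had a peak and were counted with the other genes, whose share with a peak rose from 9.92% to 9.95%. This comparison therefore leans toward a lower odds ratio. An enrichment beyond the genes first noticed was not detected in it, and the interval leaves it open.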
